A study of Mus musculus with 6 samples.

How the data were processed

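The study profiled RNA from virus-specific CD4+ T cells of mice by sequencing. Transgenic T cells of a single receptor specificity were sorted from spleen 5 days after infection with lymphocytic choriomeningitis virus (LCMV), on CD4, the congenic marker Thy1.1 and CD25, the alpha chain of the interleukin-2 receptor. The labels give 3 libraries of CD25-high and 3 of CD25-low cells, numbered 1 to 3 in each group. They do not say whether libraries come from separate animals, so the p-values measure the spread between these libraries, which may be partly technical.

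The deposited table holds raw counts, as whole numbers of reads per Ensembl gene for each library. Per the labels' protocols, total RNA was amplified with the NuGEN Ovation RNA-Seq System v2 kit. Novoalign, DESeq2 and the builds mm10 and hg19 are named in the submitters' processing notes, without a version or the role of each. The counting tool, annotation release, strand setting and treatment of reads with several matches are not given in the sources used here. The deposited counts cover 15445 genes, and the smallest row total is 10, so genes below that total have no row. Of the gene identifiers, 15169 were named through GENCODE mouse release M21, whose coordinates (GRCm38, the same assembly as mm10) are printed here, and 276 had no match.

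Total counts per library were 18847288, 18661666 and 16787233 for CD25-high libraries 1, 2 and 3, and 18810599, 23567066 and 23418118 for CD25-low libraries 1, 2 and 3. Mitochondrial ribosomal RNA took 29.26% to 35.33% of the counts. The transcript Gm42418, which overlaps ribosomal RNA sequence, took 0.35% to 2.03%. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom 33.8 to 122.5), so none was treated as a repeat deposit of another. This does not show that they are separate biological samples.

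Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with TMM factors. Low counts were removed with filterByExpr at its defaults (minimum count 10, minimum total 15), which left 12987 genes. The group was the only term. P-values were adjusted by the Benjamini-Hochberg method, and genes below an adjusted p of 0.05 were called. Standard errors (SE) of log2 fold changes were approximated as the absolute log2 fold change over the square root of F. CPM values are counts scaled by the TMM-adjusted library size. Fold changes are CD25-high relative to CD25-low.

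The numbers in the labels were tested for pairing before the calls of the fits were compared. Over the 2000 most variable genes, the deviations of same-numbered libraries from their group means correlated at 0.34, 0.19 and 0.16 for pairs 1, 2 and 3, each above the limit of 0.1 fixed for pairing, and differently numbered libraries correlated at -0.26 to 0.13. CD25-high library 2 and CD25-low library 3, at 0.13, passed that limit as well, so the check does not single out pairs 2 and 3. The numbers were still taken to pair the libraries, from the data and not from a label, and this rests mainly on pair 1. A fit with the replicate number as a block is given beside each call of a gene or list that it changes.

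Before the data were examined, 22 gene lists were fixed, together with the tests, most alternatives and the rule for named genes. The lists hold 437 different genes, some of them on several lists. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and also with an estimated correlation and with fry, which asks whether members move on balance one way and makes no comparison with other genes. Named genes are Il2ra, a fixed set of core genes, and the 8 largest rises and 8 largest falls among called genes with a mean CPM of at least 5 and no overlap between groups. Predicted genes, pseudogenes, ribosomal protein genes, small RNAs and receptor or immunoglobulin segments were left out of these. Named as well are up to 3 called members per direction of each list, or the 2 with the smallest p where none was called, and the 2 most abundant members of each list of another cell type or of stress. The values of 2 genes that the rule names are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

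Alternatives were DESeq2 1.42.0, limma voom, RLE or upper-quartile factors, library size only, no filter, a stricter filter (mean count of at least 10 and CPM of at least 1 in 3 libraries), counts thinned to 16787233 per library, removal of the 50 most abundant and the mitochondrial genes, and each library left out in turn. Further alternatives were added after the libraries numbered 1 were seen to stand apart. Shares of receptor segments carry 95% Wilson intervals, which cover counting error only.

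The fits were tested on simulated data for the CD25-high against CD25-low comparison, with 200 of 12987 genes changed and the replicate-number differences of the real libraries kept. Without the block, 1% of the 2-fold and 39% of the 4-fold changes were recovered, with 0 false calls among 40. With the block, 30% and 58% were recovered, with 1 false call among 89. The simulated data were drawn from the fit with the block, so they assume the pairing. They cannot show that the numbers pair the real libraries, or that the further calls with the block are right. In a simulation of lists of 20 genes, 5 of 5 lists raised 2-fold were recovered with either fit and 0 of 15 unchanged lists were called. These lists held random genes with independent noise. They cannot show how often camera at the preset correlation makes false calls where members move together. In the real libraries without the block, the estimated correlation was 0.71 for interferon, 0.76 for ribosome biogenesis and 0.2 for follicular helper genes. Camera with an estimated correlation recovered 5 of 5 without the block and 0 of 5 with it.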

Results

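RNA sequencing compared CD4+ T cells that carry high or low amounts of CD25 on their surface, 5 days after LCMV infection of mice. CD25 is the alpha chain that gives the interleukin-2 receptor its high affinity. All cells were transgenic T cells of a single receptor specificity, sorted from spleen, with 3 CD25-high and 3 CD25-low libraries. Total counts ranged from 16787233 to 23567066 per library. The comparison asks how antiviral CD4+ T cells that differ in CD25 differ in their transcripts.

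Il2ra, which encodes CD25 and therefore checks the labels of the sort, had 1536, 432 and 666 CPM in CD25-high libraries 1, 2 and 3, and 20.7, 29.4 and 35.7 CPM in CD25-low libraries 1, 2 and 3. Its log2 fold change was 4.94 ± 0.47 (SE), with an edgeR adjusted p of 0.00173. Il2ra (ENSMUSG00000026770) lies on the plus strand of chromosome 2 from 11642807 to 11693193 (mm10). The T cell receptor beta segment Trbv13-1 took between 95.97% (95% Wilson interval 94.65% to 96.98%) and 98.91% (97.87% to 99.45%) of Trbv counts in the 6 libraries. Trav14d-3-dv8 took between 76.08% (74.79% to 77.32%) and 85.75% (84.25% to 87.13%) of Trav counts. Trav14 copies are nearly identical, so the split of reads among them is uncertain. They do not account for the whole remainder. Trav17, which is not a Trav14 copy, took between 5.9% (5.0% to 6.95%) and 12.89% (11.5% to 14.43%) of Trav counts.

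Tox2, P2rx7, Pou2af1, Btla and Id3, on the list of follicular helper cells, which help B cells in germinal centres, were lower in CD25-high cells, while Prdm1, Il12rb2, Socs2 and Ccnd2 were higher. Largest among the rises fixed by rule were Il2ra, Socs2 (a feedback inhibitor of cytokine signalling, log2 fold change 3.57 ± 0.54), Maats1 (2.81 ± 0.42), the amino acid transporter Slc16a10 (2.79 ± 0.42), carboxypeptidase D (Cpd, 2.69 ± 0.21), the retinoid receptor Rxra (2.37 ± 0.45), Cd24a (2.08 ± 0.29) and the cyclin Ccnd2 (1.74 ± 0.24). Cpd had 148 ± 20.1 CPM in CD25-high and 22.9 ± 2.45 CPM in CD25-low cells (SD, n = 3 each). Largest among the falls were Sostdc1 (-6.49 ± 0.73), Nsg2 (-5.59 ± 0.79), the transcription factor Tox2 (-5.38 ± 0.48), the ATP-gated channel P2rx7 (-4.92 ± 0.52), F2rl1 (-4.56 ± 0.59), Degs2 (-4.30 ± 0.54), Evl (-4.30 ± 0.49) and Slfn5 (-4.24 ± 0.73). Tox2 had 1.93 ± 1.38 CPM in CD25-high and 80.9 ± 5.29 CPM in CD25-low cells (SD, n = 3 each). The rule that picked these 16 genes required a call and no overlap between the libraries of the groups. Of all tested genes, 16.9% had no such overlap.

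Tox2 (ENSMUSG00000074607) spans 163203125 to 163324170 on the plus strand of chromosome 2, and Sostdc1 (ENSMUSG00000036169) 36314139 to 36318452 on the plus strand of chromosome 12. Cpd (ENSMUSG00000020841) lies on the minus strand of chromosome 11 from 76778424 to 76847018, and Socs2 (ENSMUSG00000020027) on the minus strand of chromosome 10 from 95385362 to 95417180. Evl (plus strand of chromosome 12, 108554720 to 108688516) and Degs2 (minus strand, 108678711 to 108702315) share 278 exonic bases. The Degs2 count was 87.2% to 107% of the Evl count in the 6 libraries, so the changes of these genes cannot be taken as separate. Other called genes share exonic bases with a neighbour, among them Il12rb2 with Serbp1 (1519 bases), Slfn5 with Slfn5os (559), Ccnd2 with Gm43126 (372), Maats1 with Maats1os (305) and Ikzf2 with Gm29114 (144), all on the opposite strand, so that without a stated strand setting their counts are uncertain to that extent. P2rx7 shares 119 bases with Mir8115 on its own strand, which leaves its count uncertain too. The same holds for uncalled genes that share bases on their own strand, Foxp3 with Flicr (853) and Ifng with Gm49751 (336), and on the opposite strand, such as Il21 with Gm12534 (469).

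In all, 85 of 12987 tested genes passed an edgeR adjusted p of 0.05, 20 higher and 65 lower in CD25-high cells, and all 85 changed at least 2-fold. At an unadjusted p under 0.05 there were 1439 genes. With the replicate block, which pairs same-numbered libraries, 601 genes passed (225 higher, 376 lower), 382 of them by at least 2-fold (127 higher, 255 lower), and all 85 were among them. DESeq2, with its own filtering and 15429 genes tested, called 376 genes. Leaving out CD25-high library 1, 2 or 3 gave 130, 38 or 23 genes, and leaving out CD25-low library 1, 2 or 3 gave 49, 22 or 33. Among the 27 called genes that are named, Cpd, Degs2, Egr2, Evl, Il2ra, P2rx7, Pou2af1, Sostdc1 and Tox2 passed with any library left out, and the other 18 lost the call in 1 to 6 of these 6 fits (highest adjusted p between 0.0504 for Btla and 0.284 for Ifi27l2a). These fits had no block. With the block and without pair 1, 2 or 3, alternatives added after the data were seen, 85, 84 and 84 of the 85 genes passed. The 85 genes were chosen on these same libraries, so their passing there is no independent support.

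**Figure D1:**
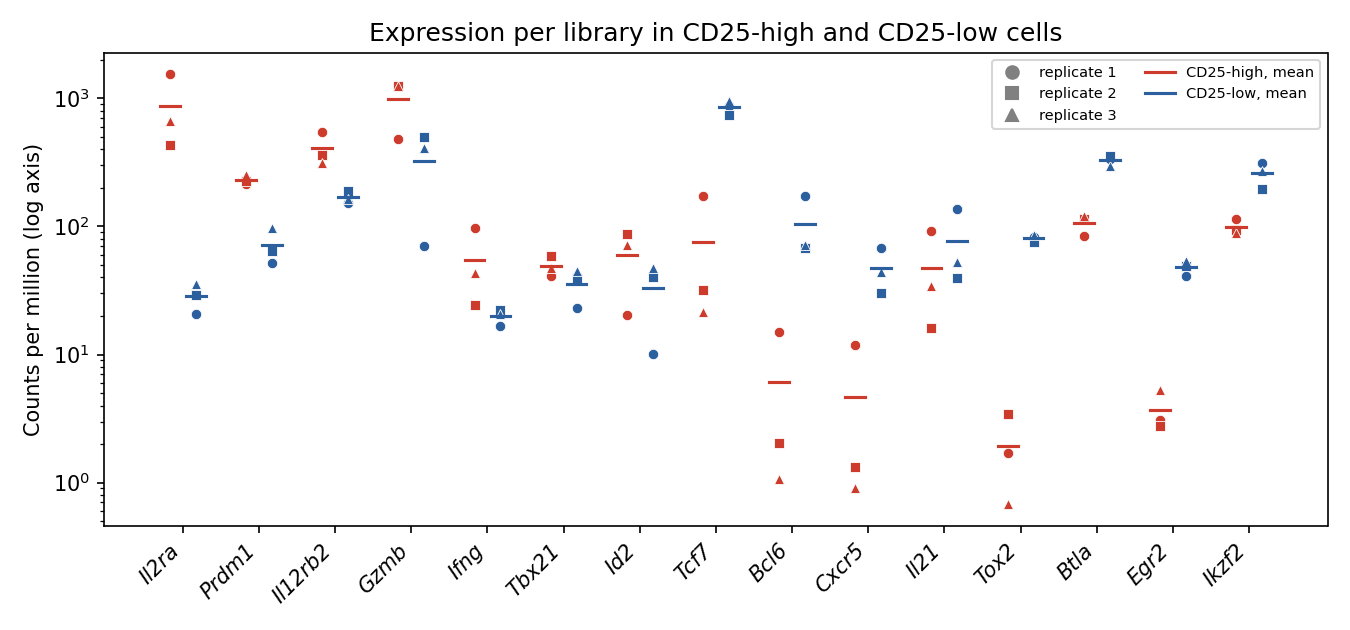
CPM (log axis) of 15 named genes in each library, CD25-high in red and CD25-low in blue, with a marker shape for each replicate number and a bar at the group mean. Il2ra lies at 432 or above in each CD25-high library and at 35.7 or below in each CD25-low library, and Tcf7, Bcl6 and Cxcr5 are higher in CD25-high library 1 than in the other CD25-high libraries.

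Follicular helper genes fell as a group in CD25-high cells. Of 25 tested members, 6 fell, among them Tox2, P2rx7, the octamer coactivator Pou2af1 (52.9 ± 6.34 against 202 ± 26.5 CPM, SD, n = 3) and the inhibitory receptor Btla (107 ± 19.0 against 329 ± 32.0 CPM), and 19 did not pass. Adjusted over the list alone 18 fell, and with the replicate block 18 fell over all tested genes. The median log2 fold change was -1.18, camera gave an adjusted p of 6.5e-18, and the adjusted p was 0.285 with an estimated correlation. Tcf7, a transcription factor of memory and follicular helper cells, had 75.6 ± 84.6 against 854 ± 108 CPM (log2 fold change -3.50 ± 0.67, edgeR adjusted p 0.0522, and 0.000142 with the block). Bcl6, the lineage-defining repressor of follicular helper cells, had 6.06 ± 7.83 against 104 ± 60.7 CPM (-4.11 ± 0.85, 0.0715, and 2e-05 with the block). Cxcr5, the receptor that guides cells to B cell follicles, had 4.69 ± 6.20 against 47.3 ± 19.2 CPM (-3.34 ± 0.82, 0.128, and 0.000269 with the block). Il21 had a log2 fold change of -0.68 ± 0.60 (adjusted p 0.738, and 0.0335 with the block). With the group as a term, 10 of the 25 members were higher and 1 lower in the libraries numbered 1 than in the others. The median log2 difference over the list was 0.34, and the camera adjusted p with an estimated correlation was 0.537.

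Among 19 tested genes of naive and central memory cells, Id3 fell (-4.64 ± 0.77) and 18 did not pass. There were 3 falls adjusted over the list alone, and 4 with the replicate block. Camera gave an adjusted p of 0.00262, and the adjusted p was 0.483 with an estimated correlation. With the replicate block and without pair 3 the list lost its call (0.121). Tcf7, Id3 and Lef1 stand on the follicular helper list too, and the memory list was not tested without them. The lymph node homing receptor Ccr7 (-0.38 ± 0.82) and the IL-7 receptor gene Il7r (1.63 ± 0.60) did not pass with either fit (edgeR adjusted p 0.909 and 0.343). Id3 lost its call without CD25-high library 2 or 3 or CD25-low library 2 or 3 (highest adjusted p 0.148).

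IL-2 receptor and STAT5-induced genes were higher as a list, which holds the sort marker. Of 23 tested members, 5 rose, Il2ra, Socs2, Ccnd2, Prdm1 and Il12rb2, and 18 did not pass. Il2ra is the sort marker, so its own place among them is no finding. Without it, a test added after the data were seen, the median log2 fold change of the other 22 was 0.58, with a camera adjusted p of 0.0125, and 0.483 was the adjusted p with an estimated correlation. The list had 10 rises and 3 falls adjusted over the list alone, and with the replicate block 10 rose and 1 fell. The median log2 fold change was 0.73, with a camera adjusted p of 0.0025, and the adjusted p was 0.483 with an estimated correlation. Prdm1, which encodes Blimp-1, a repressor of the follicular helper programme, had 231 ± 18.7 against 71.2 ± 23.5 CPM (1.69 ± 0.25, edgeR adjusted p 0.0159). It lost its call without CD25-high library 2 or 3 or CD25-low library 2 (highest adjusted p 0.121), as did Socs2, and Ccnd2 lost its call without CD25-high library 3 or CD25-low library 2 or 3 (highest 0.0917).

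Th1 effector and cytotoxic genes were higher in CD25-high cells as lists. Of 23 tested Th1 genes, 2 rose, Prdm1 and Il12rb2 (407 ± 123 against 169 ± 18.9 CPM, 1.27 ± 0.24), both also on the IL-2 list, and 21 did not pass. Adjusted over the list alone 6 rose, and with the replicate block 6 rose. The Th1 list had a camera adjusted p of 0.000779, and 0.483 was the adjusted p with an estimated correlation. Il12rb2 lost its call in all leave-one-out fits except that without CD25-high library 1 (highest adjusted p 0.177). Tbx21, the Th1 master regulator (0.46 ± 0.28), and Ifng (1.47 ± 0.43) passed in neither fit (edgeR adjusted p 0.602 and 0.216, and 0.234 and 0.0731 with the block). Id2 (0.86 ± 0.58) had an adjusted p of 0.641, and 0.0225 with the block.

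Of 17 tested cytotoxic granule genes, Serpinb9, a granzyme B inhibitor, rose (323 ± 57.5 against 124 ± 24.7 CPM, 1.38 ± 0.22) and 16 did not pass. There were 2 rises adjusted over the list alone, and 6 with the replicate block. Camera gave an adjusted p of 0.00607, and the adjusted p was 0.5 with an estimated correlation. Gzmb, which encodes granzyme B, had 992 ± 443 against 327 ± 227 CPM (1.60 ± 0.59, edgeR adjusted p 0.348, and 0.000347 with the block). Serpinb9 lost its call without CD25-high library 2 or 3 or any CD25-low library (highest adjusted p 0.147). The cytotoxic list lost its call without CD25-high library 2 (adjusted p 0.107) or CD25-low library 1 (0.339) and with the block without pair 1 (0.0556), and the Th1 list without CD25-low library 1 (0.0627). Th1 and cytotoxic genes were lower in the libraries numbered 1 than in the others, with the group as a term (median log2 differences -0.97 and -1.18).

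Type I interferon-stimulated genes fell as a group in CD25-high cells. Of 29 tested members, Stat2, which transmits interferon signals (24.8 ± 3.46 against 62.2 ± 8.13 CPM, -1.33 ± 0.23), and Ifi27l2a (31.7 ± 4.66 against 79.2 ± 19.1 CPM, -1.32 ± 0.24) fell, and 27 did not pass. Adjusted over the list alone 15 fell, and with the replicate block 19 fell. The median log2 fold change was -0.96 and the camera adjusted p 3.1e-11, and the adjusted p was 0.483 with an estimated correlation. Stat2 lost its call without CD25-high library 2 or 3 or any CD25-low library (highest adjusted p 0.216), and Ifi27l2a whichever library was left out (highest 0.284). These genes were higher in the libraries numbered 1 than in the others, with the group as a term (median log2 difference 1.10).

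Early activation genes induced through the T cell receptor were lower as a list, with 1 of 23 tested members fallen. This was Egr2 (3.69 ± 1.35 against 48.1 ± 6.77 CPM, -3.70 ± 0.33). Falls numbered 3 adjusted over the list alone, and with the replicate block 2 rose and 3 fell. Camera gave an adjusted p of 0.0227, and the adjusted p was 0.526 with an estimated correlation. The list lost its call without CD25-high library 2 (0.132) or CD25-low library 3 (0.262), with the stricter filter (0.0779), and with the block without pair 3 (0.168).

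Cell cycle genes and genes of ribosome biogenesis and amino acid transport were higher as lists, with no member passing in the fit without a block. Mcm2, a replication helicase subunit (0.62 ± 0.20, edgeR adjusted p 0.273, and 0.0486 with the block), and the mitotic cyclin Ccnb1 (0.58 ± 0.22, adjusted p 0.353) had the smallest p-values of 36 cell cycle genes. The median log2 fold change of these was 0.23, with a camera adjusted p of 0.000667 and an adjusted p of 0.483 with an estimated correlation. The cell cycle list lost its call with the replicate block without pair 2 (0.0996). Of 22 ribosome biogenesis genes, 3 rose with the replicate block, among them the amino acid transporter Slc7a5 (1.41 ± 0.45, adjusted p 0.267, and 0.00147 with the block) and Cad, of pyrimidine synthesis (0.95 ± 0.31, adjusted p 0.281, and 0.0195 with the block). That list had a median of 0.49 and a camera adjusted p of 0.00198, and the adjusted p was 0.668 with an estimated correlation. Adjusted over the list alone, 0 members passed on either list without the block. The ribosome biogenesis list lost its call without CD25-high library 1 (0.332) or CD25-low library 2 (0.0723), and its genes were higher in the libraries numbered 1 with the group as a term (median log2 difference 0.88).

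**Figure D2:**
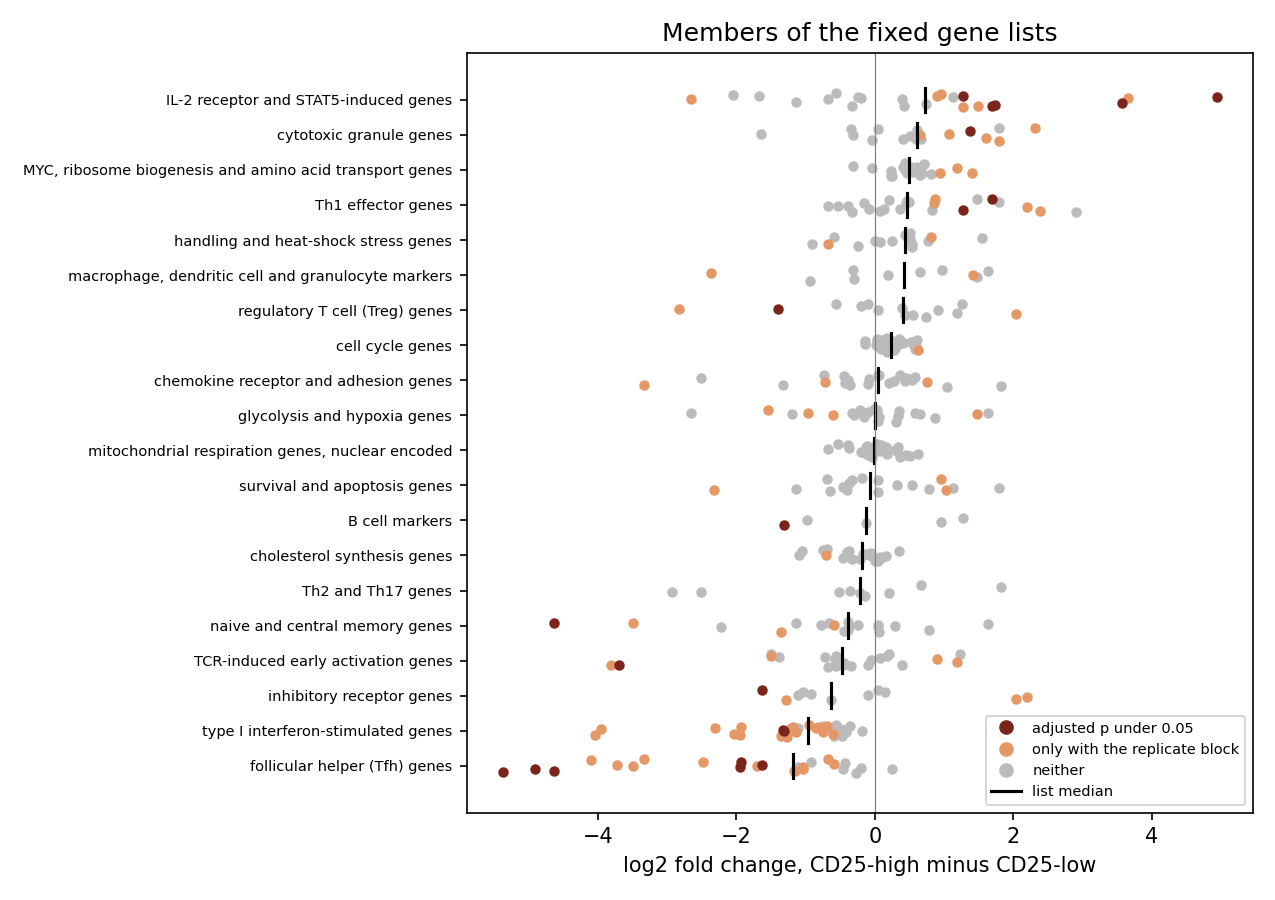
Log2 fold change (CD25-high minus CD25-low) of each tested member of the 20 lists with at least 5 tested members, ordered by the list median (black bar). Dark points passed an adjusted p of 0.05, orange points passed with the replicate block alone, and the follicular helper list has the lowest median at -1.18.

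Of the 20 lists tested, 9 were called by camera with the preset correlation, 5 higher and 4 lower in CD25-high cells, and 0 with an estimated correlation. With the replicate block 9 were called as well, and 0 with an estimated correlation. In the simulation that last test recovered 0 of 5 raised lists with the block. Its lack of calls in fits with the block therefore cannot decide whether a list changed. Fry called 3 lists, those of IL-2 and follicular helper genes (adjusted p 0.0404 and 0.0382) and that of inhibitory receptors (0.0404), and the IL-2 list lost this call without Il2ra (0.0771). Each of the 3 lost it in 5 of 6 leave-one-out fits (highest adjusted p 0.169 for IL-2, 0.127 for follicular helper and 0.258 for inhibitory receptor genes), and was called only without CD25-low library 3, CD25-high library 1 and CD25-high library 3, respectively. With the block fry called none of these (0.0918 each) and the interferon list alone (0.0144), and with upper-quartile factors or library size only it called 1 list, that of follicular helper genes.

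Camera did not call the other T cell lists. Ikzf2, which encodes Helios, fell among 14 regulatory T cell genes (98.8 ± 13.6 against 261 ± 58.8 CPM, -1.40 ± 0.23), and Foxp3 had 3.97 ± 1.75 against 1.65 ± 0.81 CPM (1.27 ± 0.61, edgeR adjusted p 0.49). Ikzf2 lost its call without CD25-high library 2 or 3 or CD25-low library 1 or 3 (highest adjusted p 0.193). Btla fell among 11 inhibitory receptor genes, and lost its call without CD25-low library 2 (0.0504). Camera gave adjusted p-values of 0.662 for regulatory genes, 0.128 for inhibitory receptors, 0.501 for Th2 and Th17 genes, 0.691 for homing genes, 0.792 for glycolysis, 0.792 for mitochondrial respiration, 0.0605 for cholesterol synthesis and 0.82 for apoptosis genes. Adjusted over the list alone, 1 regulatory gene rose and 2 fell, 2 inhibitory receptor genes rose and 3 fell, 1 glycolysis gene rose and 4 fell, and 1 homing and 1 apoptosis gene fell. With the replicate block, over all tested genes, 2 inhibitory receptor genes rose and 2 fell. Regulatory and homing genes each had 1 rise and 2 falls there. Glycolysis had 1 rise and 3 falls, apoptosis 2 rises and 1 fall, and cholesterol synthesis 1 fall. The homing list had a median of 0.05 and a mean of -0.14, and the respiration list a median of -0.02 and a mean of 0.01. Cholesterol synthesis genes were called lower without CD25-low library 2 (0.0056) and with the block without pair 2 (0.0173), and with an estimated correlation these adjusted p-values were 0.513 and 0.744.

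Members of these lists with the smallest p were Cxcr5 and Gpr183 for homing (-0.74 ± 0.31, edgeR adjusted p 0.417), Hk2 (1.47 ± 0.30, 0.0684) and Pdk1 (-0.97 ± 0.22, 0.094) for glycolysis, and Cyp51 (-0.71 ± 0.23, 0.267) and Sc5d (-0.75 ± 0.26, 0.316) for cholesterol synthesis. With the replicate block Hk2 rose (0.00032) and Pdk1 (0.0145) and Cyp51 (0.0404) fell. Fas (-2.32 ± 0.55, 0.118) had the smallest p of the apoptosis list, and fell with the block (0.016). Ndufa1 (-0.67 ± 0.31, 0.455) and Mdh2 (0.45 ± 0.21, 0.461) of the respiration list, and Il23r (-2.93 ± 1.28, 0.434) and Ccr4 (1.82 ± 0.81, 0.442) of the Th2 and Th17 list, passed in neither fit.

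Most markers of other cell types that are named here were low, apart from Ighm and Itgam. Ighm, an immunoglobulin heavy chain constant gene, had 333 ± 92.4 CPM in CD25-high and 826 ± 64.7 CPM in CD25-low cells (SD, n = 3 each). It fell by 1.31 ± 0.22 on the log2 scale (edgeR adjusted p 0.0273), and lost its call without CD25-high library 2 or 3 or any CD25-low library (highest adjusted p 0.231). The kappa light chain gene Igkc had 13.7 ± 8.83 against 7.04 ± 5.34 CPM (0.96 ± 0.73, adjusted p 0.686). Of 16 B cell markers 5 were tested, with a camera adjusted p of 0.241, which became 0.0475 without CD25-high library 1 and 0.0471 with the block without pair 1 (adjusted p 0.498 and 0.514 there with an estimated correlation). Of 24 myeloid markers 10 were tested (0.501). Itgam had 56.6 ± 30.9 against 21.2 ± 14.3 CPM (1.42 ± 0.62, adjusted p 0.433) and rose with the replicate block (0.0013). It shares 3450 of its 5024 exonic bases with Gm49368 on the same strand, so its count is uncertain. Mpeg1 (-2.37 ± 0.92, 0.371) fell with the block (0.0404). Cd74 (1.48 ± 0.62, 0.418) and Hmox1 (-0.32 ± 0.48, 0.863) passed in neither fit, with at most 8.29 CPM in a group mean. Cd8b1 (4.49 ± 0.91 against 2.05 ± 0.41 CPM) and Klrc1 (14.7 ± 4.24 against 10.2 ± 6.70 CPM) were the tested members of the CD8 and NK list, and Alas2 (2.55 ± 0.24 against 2.54 ± 0.76 CPM) of the erythroid and platelet list.

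Handling and heat-shock stress genes were not called as a list (15 tested, median 0.43, camera adjusted p 0.101), except without both libraries numbered 1 (0.0423, and 0.59 was that adjusted p with an estimated correlation). Hsp90aa1 had 587 ± 193 against 334 ± 88.8 CPM (0.81 ± 0.27, edgeR adjusted p 0.29) and rose with the replicate block (0.00499). Another member of the list fell with the block. Jun (1.54 ± 0.44, 0.204) and Hsph1 (0.51 ± 0.21, 0.395) passed in neither fit.

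The libraries numbered 1 stood apart from the others. With the group as a term, 931 genes differed between the libraries numbered 1 and the others (414 higher, 517 lower, edgeR adjusted p under 0.05), against 0 for number 2 and 0 for number 3 (551 and 470 at an unadjusted p under 0.05). Camera at the preset correlation called lists for each number, 6 for number 1, 4 for number 2 (ribosome biogenesis, early activation, interferon and respiration genes, all lower) and 4 for number 3 (interferon and follicular helper genes lower, Th1 and early activation genes higher). With an estimated correlation it called 0 for each, and the adjusted p of these lists was 0.537 to 0.572, 0.849 and 0.677. Without both libraries numbered 1, an alternative added after the data were seen, 380 genes differed between CD25-high and CD25-low cells (106 higher, 274 lower), all 85 among them. Camera then called 11 lists, the further ones being B cell markers, lower (adjusted p 0.0268), and stress genes, higher (0.0423), and with an estimated correlation 0 lists (adjusted p 0.432 and 0.59 for these).

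**Figure D3:**
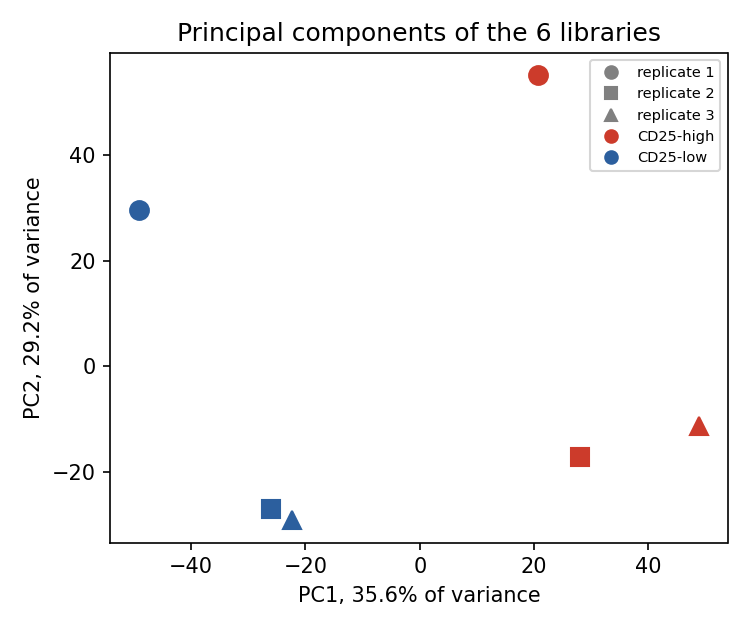
Principal components of log2 CPM over the 2000 most variable genes, CD25-high in red and CD25-low in blue, with a marker shape for each replicate number. The first component (35.6% of variance) separates the groups, and both libraries numbered 1 lie above 0 on the PC2 axis (29.2%), with the others below 0.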

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

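Alternatives that pair the block with another choice, and those without both libraries numbered 1, were chosen after the data were seen. No named gene reversed its direction where it was called under either setting. Of 583 planned values of the 65 named genes under other tools, scalings, filters and depths, 562 stayed on their side of the threshold. Of the others, 16 crossed to a call and 5 lost it. Only 27 of the 65 genes were called in the main fit and could lose a call, and 3 of them did here. The block gave 17 further calls of named genes and lost 0, it changed no list call of camera, and with fry it lost all 3 lists and gained 1, that of interferon genes. Leaving out 1 library lost 68 of 390 gene values and gained 5. The losses came from 18 of the 27 called genes, and the 38 uncalled genes had no call to lose. The cause of these changes was not tested, except that a fit without a library has fewer samples.

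The count of called genes (85) became 376 with DESeq2, which tested 15429 genes with its own filter so that tool and filter changed together, and 601 with the replicate block. Leaving out 1 library gave 22 to 130 genes, and 380 differed without both libraries numbered 1. Paired fits gave 461, 486 and 536 genes without pair 1, 2 and 3, 1064 with DESeq2, 754 with limma voom, 582 with thinned counts, 627 with RLE factors, 601 with upper-quartile factors, 606 with library size only and 624 with a GC and length correction. That correction was run on the genes with both values, where 624 passed before it as well, 576 of them shared. With at least 2-fold change, the 85 genes became 325 with DESeq2, 382 with the replicate block, 22 to 129 with 1 library left out and 322 without both libraries numbered 1. Paired fits gave 344, 392 and 413 such genes without pair 1, 2 and 3, 570 with DESeq2, 424 with limma voom, 372 with thinned counts, 395 with RLE factors, 379 with upper-quartile factors and 386 with library size only. The other alternatives gave 79 to 95 genes, and 79 to 94 with at least 2-fold change. The 9 called lists became 0 with an estimated correlation and 3 with fry, and stayed 9 with Il2ra taken off the IL-2 list.

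Differences in depth between the libraries changed the count little, since thinning to the smallest library gave 87 genes, 84 of them among the 85. Thinning cannot show whether deeper sequencing would call more genes. Other splits of the 6 libraries are too few for a share under 0.05. The real split gave 85 genes and the highest other split 0, for all called genes and for those of at least 2-fold change, so 1 of 10 splits reached the real value. For lists, 2 of 10 splits gave as many as the real 9, the other being the split that put both libraries numbered 1 and CD25-low library 3 on a side. With the block, 1 of the 4 splits that part every pair gave 601, and the highest other gave 0, and for lists the real split gave 9 and the highest other 5.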

Other observations

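The tests of cell mixture and of Ighm, and all splits, were chosen after the results were seen, and those of GC and length, depth and T cell RNA before. The libraries numbered 1 differed from the others in several gene groups, with the CD25 group as a term. Interferon-stimulated genes were higher there, 18 of 29 members, among them Oasl2 (58.2 against 8.84 and 10.1 CPM in CD25-high, 294 against 50.1 and 38.5 CPM in CD25-low cells), Ifi44 and Ifit1. Ribosome biogenesis genes were higher too, 13 of 22, among them Npm1 (log2 difference 1.30 ± 0.16) and Gnl3 (1.54 ± 0.23). Of 25 follicular helper genes 10 were higher and 1 lower, among the higher Bcl6 (2.23 ± 0.34) and Il21 (1.72 ± 0.25). Lower were 8 of 23 Th1 genes, among them Cxcr6 (-2.25 ± 0.24) and Id2 (-2.04 ± 0.23), 8 of 17 cytotoxic genes, among them Nkg7 (-1.94 ± 0.25) and Gzmb (-1.99 ± 0.26), and 13 of 24 homing genes, among them S1pr4 (-2.14 ± 0.28). Of the homing genes 1 was higher. Camera called all these lists at the preset correlation (adjusted p 7.3e-14 for interferon) and none with an estimated correlation (adjusted p 0.572 for cytotoxic genes and 0.537 for each of the others). These genes were chosen after their values were seen.

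Technical sources of that difference were tested. A correction for GC content and transcript length per library, over the 98.4% of tested genes with both values, left 773 genes different, against 933 before it, 662 of them shared. Thinning all libraries to 1 total left 968. Dilution of T cell RNA by cells of another type would lower T cell genes alike. The median log2 difference of 12 of these, such as Cd3e, Cd4 and Lck, was -0.37 (SD 0.28, lowest -0.63, highest 0.22). That is above the -1 that the 2-fold falls would need by more than the spread, but above the bound of -0.5 set beforehand by less, so a smaller dilution stays open. The labels do not say what the number stands for, so a shared day, animal or batch stays open, and no biological explanation was tested.

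CD25-high library 1 kept part of the Tcf7, Cxcr5 and Bcl6 expression of its CD25-low partner, 19.7%, 17.4% and 8.65%, against 4.37%, 4.43% and 3.01% in pair 2 and 2.28%, 2.05% and 1.5% in pair 3. An edgeR interaction test of pair 1 against the others called 5 genes, Tcf7 (adjusted p 0.0392), Ccr7, Tnfsf8, Igkc and Gm14569, on the assumption that the lone libraries of pair 1 vary like the others, with 1342 at an unadjusted p under 0.05, and Cxcr5 (0.238) and Bcl6 (0.275) did not pass. Of the 5, Ccr7 and Igkc did not keep a part of the CD25-low level but lay above it in pair 1. Ccr7 had 30.4 CPM in CD25-high library 1 against 9.46 CPM in CD25-low library 1, and Igkc 23.9 against 0.875 CPM. Both were lower in the CD25-high library of pairs 2 and 3. Admixed CD25-low cells, RNA or reads would carry every gene of the CD25-low cells at the same share or more. Of 41 genes with a fitted fall of at least 8-fold over pairs 2 and 3 together and at least 10 CPM in CD25-low cells, 22 lay below the share kept by Tcf7 with the upper end of a 95% interval of their counts below the lower end of its own, as did 16 of the 27 among them whose counts fell at least 8-fold in each of these pairs. Tox2 was at 2.06% and Sostdc1 at 2.72% in CD25-high library 1, so admixture may account for no more than about that share. The admixture test took CD25-low material as the only source, so it cannot speak to cells of another type in CD25-high library 1. Those were not tested for. A true difference in the cells of that library, whose Il2ra level was the highest, is a hypothesis that was not tested.

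Ighm was the only abundant one of the 5 tested B cell markers and was higher in CD25-low cells, which may reflect transcription in the T cells or B cells that passed the sort, although its gate on CD4 and Thy1.1 would remove them. B cells would bring light chain transcripts at a like level, but the Igkc count was at most 1.37% of the Ighm count in a CD25-low library. The log2 fold change of Ighm nearest 0 under the scaling and depth alternatives was -1.29, which argues against library size and composition. Whether the T cells transcribe the locus was not tested, and reads shared with other immunoglobulin genes stay open.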
